A study of Rattus norvegicus with 6 samples.

How the data were processed

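Gene expression was measured in cells released from the mesentery of male rats of an inbred strain, in 3 untreated samples and 3 samples taken 1 week after crocidolite exposure. Per the labels' protocols, the mesentery was digested with dispase, the suspension was passed through a nylon mesh and spun down, and total RNA was extracted on silica columns. No sort or gate is described, so the suspension could hold other cells of the mesentery beside mesothelial cells. Each sample was labelled with Cy3 and hybridised alone to 1 array. The labels gave each sample its group and its replicate number. They do not say whether the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

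The deposited scanner files hold the brightness of each spot as an intensity, written by Agilent Feature Extraction version 10.7.1.1 per the file headers (10.7 per the submitters' processing notes). The processed intensity was already background-subtracted and detrended within each array by that program, per the file headers, and was not scaled between arrays. The files also hold the mean spot intensity, the local background intensity and flags for spots that are well above background, saturated or outliers. The authors' deposited value table holds log2 values. Set against the scanner files, each of its 6 columns was log2 of the processed intensity minus 1 constant per array, for 100% of 43279 probes with a single spot, within a tolerance of 0.001. The column medians were -3.80, -3.58 and -3.91 for untreated replicates 1 to 3 and -3.68, -3.71 and -3.85 for crocidolite replicates 1 to 3, and each column's 75th percentile lay at about 0. No step of that table's making is given in the sources used here beyond the extraction program, but its scale, centring and direction follow from this match.

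Each array held 62976 spots, of which 58717 were not controls and stood for 45598 probes. Control spots and spots flagged as non-uniform or population outliers (354 to 628 per array) were left out, and 0 spots were saturated. The spots of a probe were averaged. The values analysed were log2 of the processed intensity minus the array's 75th percentile of it. A probe was kept where it was well above background on at least 3 of the 6 arrays, which left 24449 probes. A gene stood for its probe with the highest mean level, which gave 18694 genes. Of these, 4447 had several kept probes. Probe names were brought up to date through a table of current rat gene symbols (assembly GRCr8, used for names only). Of the 45598 probes, 21177 matched by accession, 9067 by symbol and 406 by synonym. For 10950 the name in the file was kept, and 3998 had no name. Positions are those of the probes in the files, on the rat build rn4 named in the file headers.

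The 2 groups were compared with limma's lmFit and eBayes (limma 3.58.1 in R 4.3.3), with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p below 0.05 and a log2 difference of at least 1. Every adjusted p printed for a gene comes from this fit unless another setting is named. Before the data were examined, 42 gene lists of 743 members were fixed, 12 of them markers of cell types. The 40 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. Counts adjusted over the list alone repeat the Benjamini-Hochberg step within a list. A gene that was not well above background on any array of one group has only a bound there. Its fold is written as "at least", from the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal.

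The rule for the genes named was fixed at the same time. It takes, among called genes with an ordinary symbol, the 12 largest differences in each direction whose probe was well above background on all 6 arrays. It adds the 5 largest bounds in each direction among called genes below background throughout one group. For each list it takes up to 4 called members, or else the members with the smallest p up to 2. It also takes Ctnnb1, Msln, Wt1, Tfrc, Fth1, Hmox1, Ccn2 and Cdkn2a whatever their values. Genes named outside this rule are said to have been chosen after their values were seen.

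All 6 arrays lay on 1 slide and were scanned together, so slide and scan could not be tested as batches. The untreated arrays lay in row 1 of the slide and the crocidolite arrays in row 2, so slide row and group cannot be told apart. The 75th percentile of the processed intensity ran from 768 to 1520, and 60.3% to 65.5% of spots were well above background. The spots of replicated probes varied with a median coefficient of variation of 3.70% to 4.76% per array. The number of arrays limits the precision.

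The fit was tested on simulated data with the spread of the 6 arrays, 200 of 18693 genes being changed. It recovered 32% of genes changed by a log2 difference of 1.5, 50% at 2, 68% at 3 and 78% at 4, and called 4 of 18493 unchanged genes. With the spread that remains without untreated replicate 3, it recovered 58%, 74%, 92% and 92%. The simulated noise was independent between genes and of equal size on all 6 arrays. The real arrays differ in both respects, so these rates may not hold for them.

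Other normalizations, background corrections, filters, variance models, probe rules and thresholds were tried, along with a replicate block and leaving out each sample in turn. Further settings were chosen after seeing the data: the mesothelial marker level as a covariate, the slide column as a block, lists without genes below background throughout one group, and an estimated correlation without untreated replicate 3. Setting the values without untreated replicate 3 beside the others throughout was also chosen then. The closing tests used numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.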

Results

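Mesothelial cells form the lining of the peritoneal cavity and are the cells from which mesothelioma arises. Crocidolite is an iron-rich amphibole asbestos. The comparison asks which transcripts differ in cells of the rat mesentery 1 week after crocidolite was injected into the peritoneal cavity. It rests on 3 untreated and 3 crocidolite samples, each on its own single-colour array. Signal was similar over the arrays, with 60.3% to 65.5% of spots well above background, and 18694 genes were tested.

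One week after crocidolite, 69 genes rose and 44 fell among the 18694 tested. The strongest statistical change was in Ptprv, a receptor-type tyrosine phosphatase. It lay at -0.15 ± 0.16 (SD, n = 3) in untreated cells and 4.95 ± 0.24 (SD, n = 3) in exposed cells on the log2 scale. Col12a1, a fibril-associated collagen, and Plod2, the lysyl hydroxylase that prepares collagen for crosslinking, also rose. The small leucine-rich proteoglycans Omd and Ogn fell, as did Cd274, which encodes the immune checkpoint ligand PD-L1. Mesothelin and Wt1, both mesothelial markers, did not pass the test.

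Ptprv rose by a log2 difference of 5.09 (SE 0.21, adjusted p = 0.00526), a 34.2-fold difference. Its probe lies on rn4 chromosome 13, from 48070489 to 48070548. Among the named genes well above background on all 6 arrays, Them5, an acyl-CoA thioesterase, came next and rose by 4.95 (SE 0.48, adjusted p = 0.0393). Jph2, a junctophilin that tethers inner membranes to the plasma membrane in muscle, and Ctnna2, an alpha-catenin that links cadherins to actin, each rose by 4.14 (SE 0.29, adjusted p = 0.0256). The other risen genes of this set were Serinc2 (3.81), the heparin-binding growth factor Ptn (3.07), the sodium channel subunit Scn4b (3.02), the opsin Opn3 (3.00), Stap2 (3.00), Ankrd34a (2.69), the glutamate receptor subunit Gria3 (2.66) and Plaat5 (2.47). Their adjusted p-values ran up to 0.0477. Each of these genes was higher in 3 of 3 crocidolite samples than in any untreated sample.

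Of the named genes that fell and were well above background on all 6 arrays, Omd had the largest difference, -4.48 (SE 0.57, adjusted p = 0.0466). It lay at 2.74 ± 0.35 (SD, n = 3) in untreated and -1.74 ± 1.12 (SD, n = 3) in exposed cells, and its probe lies on rn4 chromosome 17, from 21015198 to 21015257. Ogn lies close by, with its probe from 20987215 to 20987274 on the same chromosome, and changed by -2.94 (SE 0.39, adjusted p = 0.0477). The scaffold protein gene Akap12 changed by -3.88, PCOLCE2, which enhances procollagen processing, by -3.53, the Golgi protein gene Golm1 by -3.37 and the adrenergic receptor Adra1b by -2.93. Further falls were seen in Ccn3 (-2.31), Cd274 (-2.31), the matrix protein gene Svep1 (-2.26), Arid3b (-1.81), Ankrd6 (-1.74) and the acetyl-CoA synthetase Acss2 (-1.58). Sizes of genes well above background on all 6 arrays also moved between the settings tried. The smallest log2 difference over these settings was 2.29 for Ctnna2 and 1.04 for Ankrd34a, while Ptprv kept at least 4.51. For Ankrd6 (-0.69), Arid3b (-0.77) and Acss2 (-0.82) the smallest was under the log2 limit of 1. All 113 called genes had groups that did not overlap. Over all genes 5524, or 29.5%, did not overlap, where chance gives 10%.

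**Figure D1:**
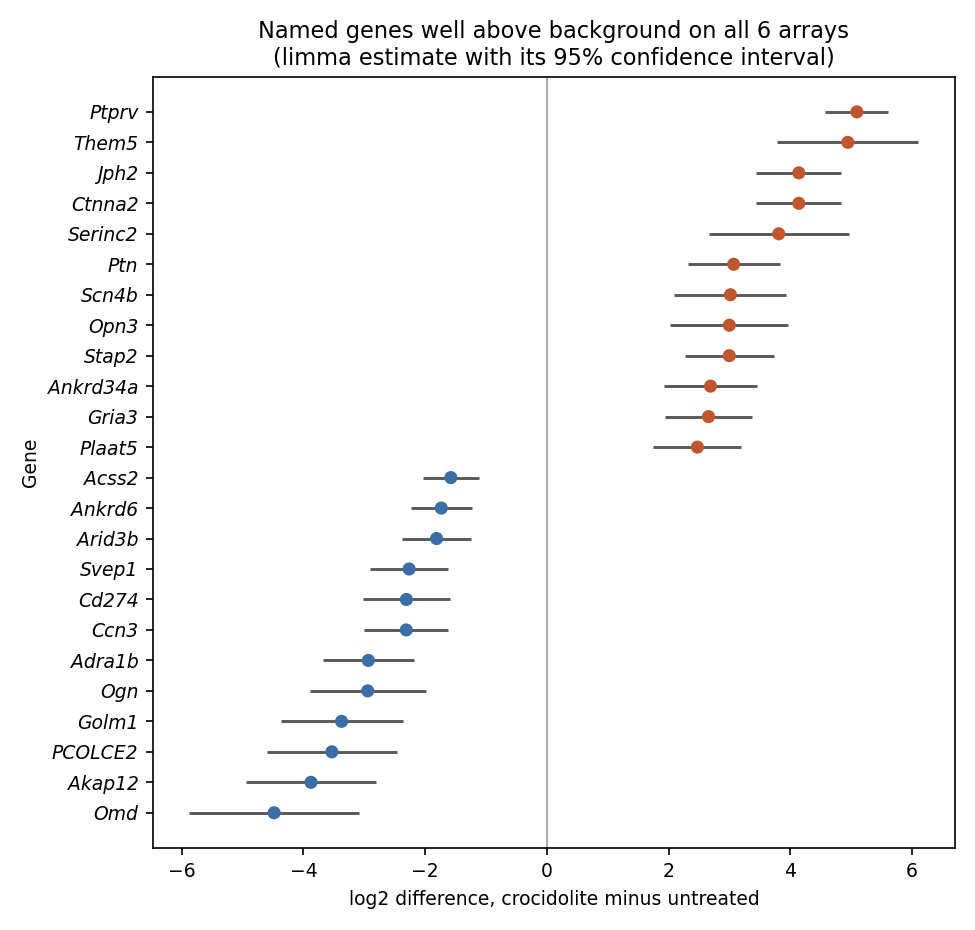
Log2 difference between crocidolite and untreated samples (x axis) for the 24 named genes well above background on all 6 arrays (y axis), with points for the limma estimate and lines for its 95% confidence interval, from 3 samples per group. The estimates run from 5.09 for Ptprv to -4.48 for Omd, and no interval reaches 0.

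Some transcripts were well above background on all exposed arrays and on no untreated array. The secreted protein gene Clca5 was at least 10.9-fold higher after crocidolite, the collagen gene Col24a1 at least 11.7-fold, C2cd4a at least 16.5-fold, Tmem196 at least 5.26-fold and the citrate transporter Slc13a5 at least 4.69-fold. In the other direction, Mrgprg was at least 6.84-fold lower after crocidolite, Mal at least 3.81-fold, Erp27 at least 3.37-fold, Ccnb1ip1 at least 2.88-fold and Rxfp3 at least 2.29-fold. Their adjusted p-values lay between 0.0327 for C2cd4a and 0.0473 for Mrgprg. These sizes depended on the background correction and on the constant of 50 that was added with normexp. Such a constant by itself shrinks the log2 differences of dim probes, and the arrays' median processed intensities were 32.5 to 65.4. With normexp background and the 75th percentile shift none of these 10 genes was called, and the fitted log2 differences ran from 0.84 for Tmem196 to 1.74 for C2cd4a and from -0.14 for Rxfp3 to -0.87 for Mrgprg, all smaller than the bounds.

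Untreated replicate 3 differed from the other 5 samples in its cell type markers. The median log2 level of the 18 tested mesothelial markers was 3.51 there, against 5.84 and 5.75 in untreated replicates 1 and 2 and 5.42 to 5.98 in the crocidolite samples. Msln, which encodes mesothelin, lay at 7.17 in this sample and at 9.13 to 9.36 in the other 5. Wt1 lay at 3.64, against 5.57 to 6.18. Across genes, which are not independent replicates, the Pearson correlation of untreated replicate 3 was 0.878 with untreated replicate 1 and 0.926 with untreated replicate 2. With crocidolite replicates 1 to 3 it was 0.906, 0.905 and 0.878. Pairs of crocidolite samples reached 0.976 to 0.982. Without this sample, limma called 1504 genes, 732 higher and 772 lower, and these held all 113 genes of the full comparison. It called 3 genes without untreated replicate 1 and 0 without untreated replicate 2 or without any 1 of the crocidolite samples, where 2230 to 2985 genes had an unadjusted p below 0.05.

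None of the 18 tested mesothelial markers rose or fell, over all genes or adjusted over the list alone. The largest differences by p were in Slpi (-1.86, SE 0.51, adjusted p = 0.136) and Calb2 (-0.92, SE 0.24, adjusted p = 0.127), the latter well above background on 1 crocidolite array. Over the settings tried, the difference of Calb2 ran from -1.12 to 0.06. Msln differed by 0.68 (SE 0.59, adjusted p = 0.549) with all samples and by -0.01 without untreated replicate 3. Wt1 differed by 0.48 (SE 0.69, adjusted p = 0.732) with all samples and by -0.34 without that sample. The list's median difference was 0.55 with all samples and -0.25 without untreated replicate 3 (camera adjusted p = 0.787 and 0.16). Without that sample 2 members were called, both lower: Gpm6a (-1.81, adjusted p = 0.0473) and Rspo1 (-2.23, adjusted p = 0.0439), chosen after their values were seen.

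The extracellular matrix and crosslinking list had the smallest camera p. Of its 26 tested members, 2 rose, 0 fell and 24 did not pass over all genes, and 5 passed upwards when adjusted over the list alone. Col12a1 rose by 2.10 (SE 0.28, adjusted p = 0.0477), from 2.32 ± 0.05 (SD, n = 3) to 4.42 ± 0.48 (SD, n = 3), and Plod2 rose by 1.76 (SE 0.23, adjusted p = 0.0466). Members were higher on average in 24 of 26 cases, with a median difference of 0.81 (camera adjusted p = 0.000647, and adjusted p = 0.978 with an estimated correlation). Leaving out untreated replicate 3 gave a median of 1.66. The matrix list's median level was 4.15 in untreated replicate 3, within the 3.85 to 4.27 of the crocidolite samples, and 2.74 and 2.65 in untreated replicates 1 and 2. Fibroblast markers were also highest in untreated replicate 3, at a median level of 5.66 against 1.80 to 4.27 in the other 5 samples. Without untreated replicate 3, 8 members rose and 0 fell. Among those, chosen after their values were seen, were Sparc (1.96, adjusted p = 0.0213), Col5a1 (1.64, adjusted p = 0.0213) and Col6a3 (2.46, adjusted p = 0.0162).

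**Figure D2:**
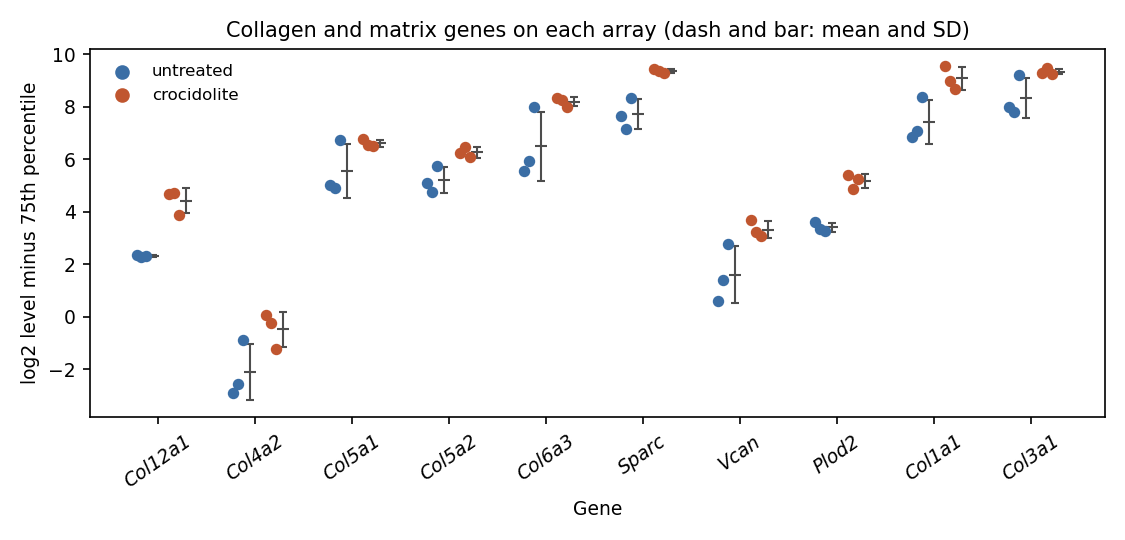
Log2 level relative to the array's 75th percentile (y axis) of the 8 matrix list members and the fibroblast markers Col1a1 and Col3a1 (x axis) that were called without untreated replicate 3, with 1 point per array and the mean and SD of 3 samples beside each group. Col12a1 lies at 2.27 to 2.36 in the untreated samples and at 3.87 to 4.70 in the crocidolite samples, while Col6a3 in untreated replicate 3 is at 8.01, against at most 8.32 in the crocidolite samples.

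Lists of related tissue remodelling gave fewer called genes. None of 18 mesenchymal transition genes passed over all genes and 3 passed upwards when adjusted over the list alone. N-cadherin, Cdh2, differed by 3.24 (SE 0.48, adjusted p = 0.0574) and S100a4 by 2.02 (SE 0.34, adjusted p = 0.0753). The list's median difference was 0.66 (camera adjusted p = 0.0363, and adjusted p = 0.978 with an estimated correlation). Without untreated replicate 3 its median was 0.60 and it did not pass camera (adjusted p = 0.0560), while 2 members rose and 1 fell. Of 8 smooth muscle and pericyte genes, 0 passed over all genes and 1 adjusted over the list alone, and all 8 were higher on average, with Acta2 at 2.61 (SE 0.61, adjusted p = 0.107) and Notch3 at 0.84. That list's median was 1.58 (camera adjusted p = 0.00252, and adjusted p = 0.978 with an estimated correlation). Its median level in untreated replicate 3, -2.78, was the lowest of the 6 samples. Matrix proteases and inhibitors had 0 of 17 genes called and a median of 0.32 (camera adjusted p = 0.874), with Adamts4 at -1.56. Ctsk, the collagen-degrading cathepsin K, lay at 2.79 ± 1.08 in untreated and 4.29 ± 0.24 in exposed cells (SD, n = 3 each). The TGF-beta and BMP list had 0 of 22 genes called (median 0.06, camera adjusted p = 0.688), with Bmp2 at 1.09 and Grem1 at 1.69. Ccn2, a common target of that pathway, differed by 0.83 (SE 0.35, adjusted p = 0.251).

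Mitotic genes were higher on average in 21 of 22 cases, but 0 passed over all genes or adjusted over the list alone. Ttk differed by 2.26 (SE 1.03, adjusted p = 0.278) and Cenpf by 1.42 (SE 0.69, adjusted p = 0.305). Over the list the median was 1.35 (camera adjusted p = 0.0218, and adjusted p = 0.978 with an estimated correlation). Untreated replicate 3 again stood apart, with a median level of 1.52 against -2.51 and -1.53 in untreated replicates 1 and 2 and -0.20 to 1.35 after crocidolite. Without it, 10 of the 22 rose, with a list median of 2.57. DNA replication genes had 0 of 19 called and 1 passing downwards adjusted over the list alone. Pcna, the sliding clamp, differed by -1.07 (SE 0.21, adjusted p = 0.0852) and Tyms by 0.61. That list's median was 0.32 and its mean 0.16, while camera, which sets it against all other genes, pointed down (adjusted p = 0.944). The list passed upwards without untreated replicate 3 (median 0.92, camera adjusted p = 0.0146, and adjusted p = 0.952 with an estimated correlation), although Pcna, its 1 called member, fell. DNA repair genes had 0 of 18 called (median 0.23, camera adjusted p = 0.688), with Apex1 at 0.67 and Mutyh at 0.59. It passed upwards without untreated replicate 3, with 2 members called (median 0.58, camera adjusted p = 0.0318, and adjusted p = 0.952 with an estimated correlation).

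Among 18 p53 targets and cell cycle inhibitors, 1 rose, 0 fell and 17 did not pass, and 4 passed upwards and 1 downwards adjusted over the list alone. The gene that rose was Zmat3, a p53-induced RNA-binding protein, by 1.66 (SE 0.21, adjusted p = 0.0461). It went from 1.41 ± 0.11 to 3.06 ± 0.24 (SD, n = 3 each), and its probe lies on rn4 chromosome 2, from 118537633 to 118537692. Cdkn2b, which encodes the cell cycle inhibitor p15, differed by 3.26 (SE 0.47, adjusted p = 0.0538). Cdkn2a, its neighbour in the genome and often lost in mesothelioma, differed by 1.00 (SE 0.96, adjusted p = 0.589), with a wide spread in untreated cells. Without untreated replicate 3 Cdkn2a differed by 1.94 (adjusted p = 0.12). For this list the median was 0.64 (camera adjusted p = 0.338).

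Markers of lymphocytes and mast cells were lower on average after crocidolite, and none was called over all genes. The 12 B and plasma cell markers had a median of -3.27, with 7 passing downwards adjusted over the list alone (camera adjusted p = 0.00252, and adjusted p = 0.978 with an estimated correlation). Ms4a1, which encodes CD20, differed by -4.82 (SE 1.38, adjusted p = 0.147) and Cd79b by -4.23 (SE 1.36, adjusted p = 0.174). For the 12 T and NK cell markers the median was -1.99 (camera adjusted p = 0.00745, and adjusted p = 0.978 with an estimated correlation), with 0 adjusted over the list alone, Cd3d at -2.45 and Gzmb at -2.46. The 11 mast cell markers had a median of -1.54 (camera adjusted p = 0.00502, and adjusted p = 0.978 with an estimated correlation), with 0 adjusted over the list alone, Tpsb2 at -2.06 and Ms4a2 at -2.46. The untreated samples were far apart on these markers. The median level of the B and plasma cell list was 0.73 in untreated replicate 2 and 2.63 in untreated replicate 3, against -3.79 to -2.07 after crocidolite, and untreated replicate 1 lay just above that range. For T and NK cells untreated replicate 1, at -1.28, lay within the crocidolite range of -1.48 to -0.12, and for mast cells, at -0.87, within that of -1.02 to 0.57. Ms4a1 was well above background on 1 crocidolite array, and Gzmb and Ms4a2 on 2. Without untreated replicate 3 the medians were -2.32 for B and plasma cells, -1.05 for T and NK cells and -1.33 for mast cells, and none of these 3 lists passed camera (adjusted p = 0.0649, 0.148 and 0.0769). Cd3d then differed by -1.47 and Gzmb by -1.61.

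**Figure D3:**
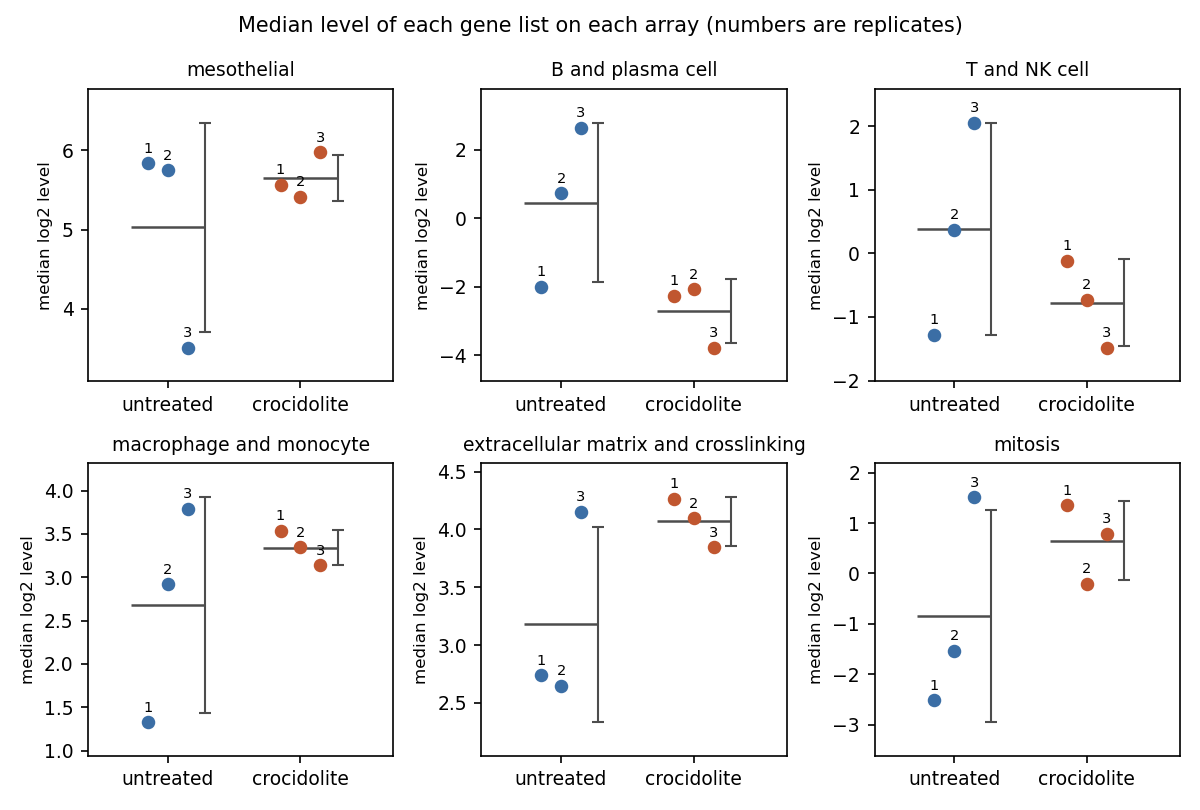
Median log2 level relative to the array's 75th percentile (y axis, scaled separately in each panel) of 6 gene lists on each of the 6 arrays (x axis, by group), with a number for the replicate and a line and bar for the mean and SD of 3 samples. Untreated replicate 3 has the lowest mesothelial level, 3.51, and the highest B and plasma cell level, 2.63.

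The other cell type lists did not pass. Of 18 macrophage and monocyte markers, 0 passed over all genes and 1 passed downwards adjusted over the list alone, with Spp1 at 2.27 (SE 0.56, adjusted p = 0.113) and the growth factor receptor Csf1r at -1.50 (SE 0.29, adjusted p = 0.0852). Its median was 0.59 (camera adjusted p = 0.683), and its median level in the untreated samples ran from 1.33 to 3.79. Leaving out untreated replicate 3 gave a median of 1.02 (camera adjusted p = 0.0769), with Csf1r called lower. The endothelial list had 0 of 12 genes called, a median of 0.07 and a mean of -0.14 (camera adjusted p = 0.879), with Tek at -1.13 and Robo4 at 0.75. The fibroblast list had 0 of 12 called, 1 passing downwards adjusted over the list alone, a median of 0.19 and a mean of -0.21 (camera adjusted p = 0.914), with Dpep1 at -3.34 (SE 0.49, adjusted p = 0.0560) and Col1a1 at 1.64 (SE 0.47, adjusted p = 0.147). Its median was 0.89 without untreated replicate 3, where 2 members were higher, among them Col1a1 (2.12, adjusted p = 0.0264), and Dpep1 was lower (-2.92, adjusted p = 0.0252). The adipocyte list had 0 of 8 called, 1 passing downwards adjusted over the list alone and a median of -0.84 (camera adjusted p = 0.125), with Lpl at -2.03. Adipoq was well above background on no crocidolite array and at least 3.30-fold lower there (adjusted p = 0.155). The erythroid list had 0 of 5 called and a median of -1.72 (camera adjusted p = 0.6), with Ahsp at 0.78 and Hbb at -2.96, the latter well above background on 2 untreated arrays and 1 crocidolite array. Without untreated replicate 3 the erythroid median was -0.23, that of the endothelial list 0.29 and that of the adipocyte list -0.42. The neutrophil and eosinophil lists kept 4 tested genes each and were not tested as lists. Their medians were -1.48, with S100a8 at -1.58 and S100a9 at -1.89, and 0.11, with Alox15 at 2.90 (SE 0.54, adjusted p = 0.0843) and Siglec5 at -1.42. Adjusted over the list alone, Alox15 passed upwards. The medians of these 2 lists were -0.93 and 0.49 without untreated replicate 3, where S100a8 differed by -0.91 and S100a9 by -1.14.

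Iron handling was of interest because crocidolite fibres carry iron. None of 24 iron genes passed over all genes, and 1 passed downwards adjusted over the list alone. The transferrin receptor Tfrc differed by -1.05 (SE 0.18, adjusted p = 0.0787), and all 3 crocidolite samples lay below all untreated ones. Tfrc was called lower without untreated replicate 3 (-1.04, adjusted p = 0.0347), as were 2 other members of the list. Fth1, the ferritin heavy chain, differed by 0.49 (SE 0.20, adjusted p = 0.237), Hmox1, which breaks down haem, by -0.43 (SE 0.20, adjusted p = 0.282) and the iron regulatory protein Aco1 by 0.71 (SE 0.19, adjusted p = 0.133). The iron list's median was 0.18 and its mean -0.11 (camera adjusted p = 0.923). The ferroptosis and glutathione list had 0 of 15 genes called and 1 upwards adjusted over the list alone (median 0.34, camera adjusted p = 0.325), with Gss at 0.94. NRF2 targets had 0 of 16 called and 1 upwards adjusted over the list alone (median 0.12, mean -0.13, camera adjusted p = 0.735), with Abcc4 at 1.41 (SE 0.23, adjusted p = 0.0709) and Nqo1 at -0.71. The medians without untreated replicate 3 were 0.12 for iron handling, 0.18 for ferroptosis and glutathione and 0.01 for NRF2 targets.

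With all samples, no inflammation list had a called gene. Chemokines and acute cytokines had a median of -0.16 and a mean of 0.08 over 25 genes (camera adjusted p = 0.688), with Il6 at -2.19 (SE 0.50, adjusted p = 0.103) and the alarmin Il33 at -2.47 (SE 0.70, adjusted p = 0.144). The NF-kB list had a median of -0.16 and a mean of 0.05 over 18 genes (camera adjusted p = 0.787), with Vcam1 at 2.63 and Cd40 at -1.01. That list passed downwards without untreated replicate 3 (median -0.43, camera adjusted p = 0.0346, and adjusted p = 0.952 with an estimated correlation), with 4 members lower and 1, Vcam1, higher. The NLRP3 inflammasome list had a median of -0.16 over 10 genes (camera adjusted p = 0.879), with Gsdmd at 0.92 and Nek7 at 0.45. The interferon list had a median of 0.12 over 21 genes (camera adjusted p = 0.879) and 1 gene passing in each direction adjusted over the list alone. Its members Bst2 and Irf8 differed by 1.48 and -1.38. Antigen presentation had a median of 0.01 and a mean of -0.12 over 13 genes (camera adjusted p = 0.944), with Tapbp at 0.66 and B2m at 0.31. Complement had a median of -0.06 and a mean of 0.42 over 16 genes (camera adjusted p = 0.874). Its regulator Cfi differed by 3.99 (SE 0.83, adjusted p = 0.0929), passing adjusted over the list alone, and C3 differed by 2.62. Leaving out untreated replicate 3 turned the medians of the chemokine list to 0.19 and of the inflammasome list to 0.17, and gave 0.25 for interferon and 0.54 for antigen presentation.

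Signalling lists also held no called gene with all samples. The WNT list had a median of -0.09 over 24 genes (camera adjusted p = 0.519) and 1 gene passing downwards adjusted over the list alone. Beta-catenin itself, Ctnnb1, differed by 0.27 (SE 0.23, adjusted p = 0.552), Myc by -1.43 (SE 0.26, adjusted p = 0.0820) and Wnt5b by -1.09. YAP and TEAD targets had a median of -0.28 over 13 genes (camera adjusted p = 0.519), with 1 passing downwards adjusted over the list alone, tissue factor F3 at -2.47 (SE 0.49, adjusted p = 0.0878) and Amotl2 at -1.16. These targets passed downwards without untreated replicate 3, with 3 members called lower (median -0.77, camera adjusted p = 0.0318, and adjusted p = 0.952 with an estimated correlation). The growth factor list had a median of -0.02 over 19 genes (camera adjusted p = 0.879), with 2 passing downwards adjusted over the list alone, Fgf2 at -1.94 (SE 0.39, adjusted p = 0.0878) and Igf2 at -1.14, whose other probe pointed the opposite way. Immediate early genes had a median of -0.21 over 19 genes (camera adjusted p = 0.193), with 2 passing downwards adjusted over the list alone, Myc as above and Zfp36 at -1.24. These 2 were called lower without untreated replicate 3, where the list passed downwards (median -0.49, camera adjusted p = 0.0346, and adjusted p = 0.952 with an estimated correlation). Heat shock genes had a median of 0.05 over 11 genes (camera adjusted p = 0.879), with Dnajb1 at -0.81 and Hspb1 at 0.75. The WNT median was -0.17 and the growth factor median -0.42 without untreated replicate 3.

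Of the housekeeping and metabolic lists, ribosomal protein genes stood lower on average. Their median was -0.41 over 20 genes, 16 of them lower on average and 0 called (camera adjusted p = 0.00252, and adjusted p = 0.978 with an estimated correlation), with Rps4x at -0.78 and Rps6 at -0.68. The list's median level was 7.89 in untreated replicate 1, within the 7.67 to 7.96 of the crocidolite samples. In untreated replicates 2 and 3 it was 8.20 and 8.26. The lysosome and phagocytosis list had 0 of 21 called and a median of 0.40 (camera adjusted p = 0.0802), with Trem2 at 2.11 and Ctsl at 0.81. It too passed upwards without untreated replicate 3, with 0 members called (camera adjusted p = 0.0318, and adjusted p = 0.952 with an estimated correlation). Tight and adherens junction genes had 0 of 13 called and a median of 0.58 (camera adjusted p = 0.193), with Dsp at 1.79 and Cldn4 at 1.74. The junction list's median level was -0.34 in untreated replicate 3 and 1.37 to 2.19 in the other 5 samples, and without that sample its median difference was 0.05 and that of Dsp 0.67. Such medians were 0.22 for oxidative phosphorylation and 0.33 for the unfolded protein response. Fatty acid oxidation had 0 of 17 called and a median of 0.32 (camera adjusted p = 0.193), with Acads at 1.04 and Cpt2 at 0.63. Glycolysis and hypoxia had 0 of 21 called and a median of 0.24 (camera adjusted p = 0.735), with Car9 at 1.47 and Pfkp at -0.61. Oxidative phosphorylation had 0 of 22 called and a median of 0.07 (camera adjusted p = 0.879), with Atp5mc1 at 0.42 and Sdhb at 0.39. The unfolded protein response had 0 of 16 called and a median of 0.12 (camera adjusted p = 0.879), with Atf4 at -0.71 and Calr at 0.67. The circadian clock had 0 of 15 called and a median of -0.45 (camera adjusted p = 0.159), with Npas2 at -1.08 and Per1 at -0.53.

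Of the 651 list members tested, 3 were called, and 8 of 40 lists passed camera with its preset correlation. Without untreated replicate 3, 10 lists passed, and 4 of these were among the 8: matrix, smooth muscle, mitosis and ribosomal proteins. Of the named genes that did not pass with all samples, Il6, Npas2, Cfi, Pcna, Alox15, Acads, Car9, Bst2, Ctsk, Cdh2, S100a4, Abcc4, Cdkn2b, Grem1, Atf4, Wnt5b, Amotl2 and F3 were among those called without that sample, each in the same direction as with all samples. Camera with an estimated correlation passed 0 lists, and 0 had an unadjusted p below 0.05. Fry passed 0 lists, with 5 at an unadjusted p below 0.05. Across all genes, limma gave an unadjusted p below 0.05 for 3792.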

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

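The mesothelial covariate, the slide column block and the settings that join an estimated correlation with leaving out untreated replicate 3 were tests chosen after the result was seen. The 113 genes called (69 higher, 44 lower) kept their direction in every setting that tested them, except 1 gene that turned with the dimmest probe of each gene. Much of this was fixed in advance. Their groups did not overlap, so leaving out 1 sample could not turn a sign. The replicate block, trend with robust eBayes and the changed thresholds reuse the same log2 differences. Quantile normalization (127), median shift (109), the authors' value table (113), outlier spots kept (113), no log2 limit (113), the mean of all probes (105) and normexp with quantile normalization (124) gave counts within 1.5 times, the last with only 58 of the 113 among them. Others moved the count further. Normexp with the 75th percentile shift called 39 genes (22 higher, 17 lower), no filter on dim probes 4 (4 and 0, with 8 lists lower), the filter at all 6 arrays 70 (46 and 24), trend with robust eBayes 58 (43 and 15) and array weights, whose estimation stopped before it converged, 3153 (1350 and 1803). The dimmest probe gave 78 (50 higher), within 1.5 times, but its lower count, 28, was not. An adjusted p below 0.01 left 1 gene (1 higher, 0 lower), and treat against a log2 difference of 1 left 1 (1 and 0). The mesothelial marker level as a covariate gave 1252 genes (662 higher, 590 lower), all 113 among them. That level was 3.51 in untreated replicate 3 and 5.42 to 5.98 in the other samples, so the covariate mostly marks that sample. Its count is therefore not separate from the one without untreated replicate 3. The share of higher calls, 61.1% here, was 74.1% with trend and robust eBayes and 42.8% with array weights. The array weights were 10.1 for untreated replicate 2, 0.52 and 0.12 for untreated replicates 1 and 3, and 0.79 to 1.63 for the crocidolite samples. The untreated mean of that fit thus rested mostly on 1 sample. Beyond this, the cause of the changes in counts and shares was not tested.

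With the replicate block limma called 0 genes (0 higher, 0 lower), with 2594 at an unadjusted p below 0.05. The deviations of same-numbered samples from their group means correlated across genes at -0.46, 0.21 and -0.38. Deviations of 3 samples from their mean are not independent, and untreated replicate 3 stood apart. These values therefore cannot show whether the numbers pair the samples. With the slide column as a block limma called 0 genes (0 and 0), with 1474 at an unadjusted p below 0.05. Only slide columns 2 and 3 held arrays of both groups, so this block left little to compare. It cannot show whether slide column plays a part. Leaving out 1 sample at a time gave 0 to 1504 genes (0 to 732 higher, 0 to 772 lower) and 2 to 6 lists higher. The 1504 came without untreated replicate 3. With an estimated correlation 0 lists passed (0 higher, 0 lower), with fry 0 (0 and 0), and with an estimated correlation without untreated replicate 3 it was 0 (0 and 0). For the DNA replication list, camera's direction turned from down (adjusted p = 0.944) to up without untreated replicate 3 (adjusted p = 0.0146, and 0.0146 to 0.875 when each sample was left out). The list's median difference was above 0 in both cases, at 0.32 and 0.92. Among named genes, 2383 values kept their side of the threshold, 428 lost it and 122 gained it. Among lists the counts were 933, 39 and 26. A block for the slide was planned and could not be fitted, since all arrays shared 1 slide. Signal over background limits the genes that were dim in one group, which have only bounds.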

Other observations

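All tests of explanations in this part were chosen after the result was seen, and the genes in the next 2 paragraphs were chosen after their values were seen. Pcolce, which enhances cleavage of the procollagen end, rose by 1.93 (SE 0.21, adjusted p = 0.0434), from 6.43 to 8.36, while its relative PCOLCE2 changed by -3.53. P3h4, a partner of collagen-modifying enzymes, rose by 1.95 (SE 0.26, adjusted p = 0.0479). Duox2, a hydrogen peroxide producing oxidase, rose by 4.99 (adjusted p = 0.0473), and Duoxa2, its maturation factor, was at least 2.81-fold higher (adjusted p = 0.0461). Duox2 was well above background on 1 untreated array and Duoxa2 on none. Ace, which makes angiotensin II, rose by 2.31 (SE 0.24, adjusted p = 0.0393).

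Without untreated replicate 3, limma called 71 of the 651 list genes, 40 higher and 31 lower, where it called 3 with all samples. The monocyte chemokine gene Ccl12 was then higher by 6.05 (adjusted p = 0.0154), the adhesion molecule Vcam1 by 3.31 (adjusted p = 0.0212) and the interleukin-1 antagonist Il1rn by 3.00 (adjusted p = 0.0439). Il6 was lower (-1.68, adjusted p = 0.0379), as was Lcn2 (-4.86, adjusted p = 0.0187). Of mitotic genes, Ttk was higher by 3.42, Tpx2 by 2.88 and Cdk1 by 2.65. With all samples none of these 8 genes passed, and their adjusted p-values ran from 0.103 for Il6 to 0.402 for Lcn2.

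The first pattern was the distance of untreated replicate 3 from the other untreated samples. A dim array was argued against by its 75th percentile signal of 1263, above the lowest other array at 768. A lower share of mesothelial cells alone was argued against by marker shifts. The median shift of its B and plasma cell markers exceeded that of its mast cell markers by 2.57. The two-sided permutation p was 0.01 over genes, which are not independent, and the SE of the difference of means was 0.58. Of the 1504 genes that differed most, at least 45.5% were nearer to untreated replicates 1 and 2, against 6.25% to 15.8% for a left-out crocidolite array. Of the 3 genes with the lowest adjusted p without this sample, Ptprv (-0.33, against 4.76 to 5.21 in crocidolite) and Them5 (-4.02, against 1.73 to 2.18) lay there on the untreated side and Tex26 (-4.02, against -5.15 to -4.45 in crocidolite and 0.78 to 0.80 in untreated replicates 1 and 2) on the crocidolite side. A mislabelled crocidolite sample stays open, since a sample apart from both groups would give such a mixture under either label; a different mix of cells may also remain as a hypothesis, and a difference between animals was not tested.

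The second pattern was pancreatic enzyme transcripts. Trypsinogen Prss2 fell by 7.08 (adjusted p = 0.0461; well above background on 2 crocidolite arrays), and was chosen after its value was seen. Of 24 acinar enzymes listed, Prss2 and 8 others were tested. Those 8 were higher in untreated replicate 1 than in untreated replicate 2 by a median of 3.35. This differed from Prss2 by 0.33 (SD 0.68), so acinar cell RNA could account for these 2 samples. For untreated replicate 3 the same source was argued against over the 8 as a set, since their median change differed from that of Prss2 by -3.78 (SD 2.04). Their changes from untreated replicates 1 and 2 ran from -7.61 to -1.19, against -0.46 for Prss2. The smallest, -1.19, was that of Prss3, which lay near Prss2. Prss3 also had a similar difference after crocidolite (-7.31, adjusted p = 0.0574). Cela3b, of the same list, was higher in the crocidolite samples, at 4.28 to 5.09.

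The third pattern was the rise of Ptprv, Zmat3 and Eda2r (at least 2.01-fold, adjusted p = 0.0393), which are known p53 targets. Each kept at least 96.6% of its difference without untreated replicate 3, so the rise did not rest on that sample. The lowest share was that of Eda2r, which has only a bound. Genes called with that sample included could hardly come out otherwise, since all 113 of them stayed called without it. No conclusion on the makeup of that sample is drawn from this. A second list of p53 targets, without Ptprv and Eda2r, had a median of 0.18 over 33 genes, at percentile 84.9 of 10000 random lists of matched level (bootstrap interval -0.03 to 0.45), and at 96.1 with those 2 genes (83.2 without untreated replicate 3). The value of 84.9 lay inside the range first set as counting against a wider p53 response, and the question was left open only after it was seen, because the interval reaches past 0.25, the 95th percentile of the random lists. The p53 list fixed at the start, which also holds cell cycle inhibitors, stood at percentile 99.89 without Zmat3 (median 0.55). Without Zmat3, 10 of its 17 members were higher on average. Random lists ignore the correlation between genes. This was estimated at 0.000107 for the whole list, but from 6 arrays only, so the estimate cannot show that the limit is small. The members of the whole list were split, 11 higher and 7 lower on average, and camera gave the whole list an adjusted p of 0.338. A wider response may therefore be present or not.

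The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, 1 split, the real one, gave 113, and the highest other gave 0 (2241 at an unadjusted p below 0.05 against 3792). For lists the real split gave 8 and the highest other 20, and 8 of the 10 splits gave at least as many as the real one.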
